A study of Mus musculus with 8 samples.

How the data were processed

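H2A.X, a histone variant that is phosphorylated at DNA breaks, was profiled by native chromatin immunoprecipitation and sequencing in mouse embryonic stem (ES) cells. Per the labels' protocols, chromatin was digested with micrococcal nuclease and precipitated with 0.5 µg of an antibody to H2A.X. The 8 samples hold 1 library per condition. They are DNMT1 knockout (KO) cells in serum, wild-type cells in 2i medium, wild-type cells in PKCi medium, wild-type cells in SRCi medium, and 2 pairs in serum, TDG control with TDG knockdown (KD) and TKO control with TKO. TKO is used as the labels give it, which do not spell it out. Serum medium held 15% fetal bovine serum. PKCi medium held 5 µM Gö6976, a protein kinase C inhibitor. SRCi medium held 1.5 µM CGP77675, a Src kinase inhibitor, and 3 µM CHIR99021, a GSK3 inhibitor.

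The deposited files are 6 lists of domains, each made by the authors from a pair of libraries. Reads were aligned with Bowtie2 2.0.6 to mm9, per the submitters' processing notes. The program that called the domains, its settings and any scaling for sequencing depth are not given in the sources used here. Each deposited line holds a domain on a grid of 1 kb, a mark for the library in which it was enriched, a signed score and a second score summed over the domain's bins. Both columns are the authors' own scores, with no unit stated per the labels or in the lists, and they were used only to describe and rank domains within a list. The signed score rises toward the first library of the list and falls toward the second, around a list-wide offset, so its sign alone does not give the side. Which library is first was taken from the order of the conditions in each list's name, because the lists carry no header. Every direction given for a list rests on that order. The libraries of serum wild-type cells and of the DNMT1 control were not analysed here as samples of their own, and enter only through the lists.

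In each list the length-weighted median of the signed score lay away from 0, and the side it points to is called the offset side. Domain numbers, covered length and lengths were computed per side. Percentages of the genome refer to the 2655 Mb spanned by the chromosomes as the lists reach them. All 60 pairings of sides from different lists were compared by the number of domains of the first side that met the second by at least 1 base, and by shared bases. Each value was set against 1000 circular shifts of the second list within each chromosome, a permutation test with a two-sided p and Benjamini-Hochberg adjustment over the 60 pairings. The smallest p that these shifts can give is 0.00200. The direction of overlapping domains in the 15 pairs of lists was given as a log2 odds ratio beside its value under shifts. Net coverage in 1 Mb bins of chromosomes 1 to 19 and X, first side minus second, was compared by Spearman's rho, and coverage of the last 5 Mb of chromosomes was compared with shifts. Neighbouring bins are not independent. Length and score of domains that met another list were compared with those of the rest by label permutation within chromosomes, with 100000 resamples. These tests compare places between lists and not conditions, and lists that share a library share its noise. With 1 library per condition no p-value is given for any change between conditions. Shares of domains carry Wilson 95% intervals, which cover counting error only.

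The overlap count and the label permutation were tested on simulated data. Shared bases, direction odds, rho and coverage of chromosome ends were not. Simulated domains were placed uniformly along chromosomes, which real domains need not be. For the DNMT1 KO side against the 2i side of the serum list on the autosomes (1470 and 5984 domains), 1 of 100 random placements gave p under 0.05, with a mean ratio of 1.00. With 200 domains placed on domains of the other list, 20 of 20 simulations passed and 199 domains were recovered on average. The label permutation passed in 4 of 100 simulations of 600 domains with no difference.

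Alternatives chosen before the data were examined were the 50% of domains with the highest score toward their side, merging within 10 kb, autosomes only, an overlap of 50% of the shorter domain, uniform random placement, pooled directions, covered bases in place of counts, bins of 5 Mb and the last 10 Mb of chromosomes. An alternative chosen after seeing the data used autosomes without chromosomes 6, 8 and 11 and without empty blocks, and is called the reduced autosomes. Empty blocks are domains with a signed score within 0.05 of 0 in the 3 lists that name 2i, 32 blocks spanning 56.3 Mb. The notion of an offset side was also chosen after seeing the data, as were the 15 pairings followed through the alternatives. The rule for named regions, set before the data were examined, took the 5 longest and the 5 highest-scoring domains per side and the 5 longest regions shared by 3 or more lists; a few of each are printed. Coordinates are on mm9 and count from 1. Gene annotation on mm9 was not used here, so regions are named by position, and the planned gene lists were not tested. Sequencing depth is unknown, since the lists hold no read counts. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.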

Results

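A total of 6 lists of H2A.X domains were compared, together holding 25499 domains. Each list sets a pair of ES cell libraries against each other: DNMT1 control and DNMT1 KO, serum and 2i, 2i and PKCi, 2i and SRCi, TDG control and TDG KD, and TKO control and TKO. Every condition had 1 library, so no difference between conditions has a replicate check, and read depth is unknown. A domain is called higher in a library by the mark in its list, and not by absolute signal. In every list the offset lay between the score quartiles of the side opposite the offset side, so it does not part the sides. All regions are mm9 positions without gene annotation.

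Loss of DNMT1, the enzyme that maintains DNA methylation through cell division, gave 1499 domains higher in the knockout and 2631 higher in its control. The knockout domains were short, with a median of 43 kb against 242 kb, and covered 89.5 Mb against 1254 Mb. The longest knockout domain was chromosome 11, 30506001 to 31171000, at 665 kb, followed by chromosome 17, 22566001 to 23063000, at 497 kb. The longest control domains lay on X and Y, led by X, 35168001 to 49756000, at 14.6 Mb. That on Y, 2903001 to 15902000, at 13.0 Mb, is an empty block. The control side covered 85.2% of X, where the knockout side covered 0.323%. The median signed score was -6.58 in knockout domains and -2.58 in control domains, so control domains were mostly those in which the score leaned less toward the knockout. The list's score offset was -2.66.

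In wild-type cells, 2i medium gave 6137 domains above serum, and serum gave 4483 above 2i. The 2i domains had a median length of 14 kb and covered 294 Mb, and the serum domains 97 kb and 921 Mb. The 2i domains were concentrated on chromosome 6, of which they covered 68.0%, and chromosome 8, of which they covered 64.1%. On the other 17 autosomes they covered 3.29% to 9.61%. Their longest were chromosome 6, 105443001 to 108505000, at 3.06 Mb, and chromosome 6, 43886001 to 46628000, at 2.74 Mb. By count, chromosomes 6 and 8 held 1356, 22.1% (Wilson 95% interval 21.1% to 23.2%), of the 2i domains. Of the serum domains, 4465 had scores below 0 (median -7.55, offset -7.76), toward 2i. They were marked as higher in serum beside 2i domains with a median score of -20.3. The serum side covered 2.16% of chromosome 6, 5.59% of chromosome 8 and 93.2% of X. On chromosomes 6 and 8 these serum bases were mostly empty blocks. Their mean scores, weighted by length, were -0.0413 and -0.417, against -6.75 on X.

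Media with a protein kinase C inhibitor (PKCi) or a Src kinase inhibitor (SRCi) gave broad domains marked as higher than in 2i. PKCi domains numbered 2527, with a median of 413 kb, and covered 2019 Mb, or 76.0% of the genome. SRCi domains numbered 3175, with a median of 333 kb, and covered 2057 Mb, or 77.5%. Scores were above 0, toward 2i, in 2508 PKCi domains (median 4.95, offset 5.05) and 3149 SRCi domains (median 6.11, offset 6.04). The score itself thus shows no gain over 2i in these domains, but scaling is unknown and 0 need not mean no difference. These domains hold most of the covered length and so largely set the offset. A median close to the offset therefore says nothing further about them. The 2i side held 693 domains against PKCi and 585 against SRCi, covering 158 Mb and 177 Mb. Chromosomes 6 and 8 again carried most of these, at 51.0% and 57.1% of their length against PKCi and 58.3% and 62.5% against SRCi, where no other autosome exceeded 0.769% and 1.02%. The longest 2i domain over SRCi was chromosome 8, 98566001 to 106325000, at 7.76 Mb, and over PKCi chromosome 8, 98885001 to 104635000, at 5.75 Mb.

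**Figure D1:**
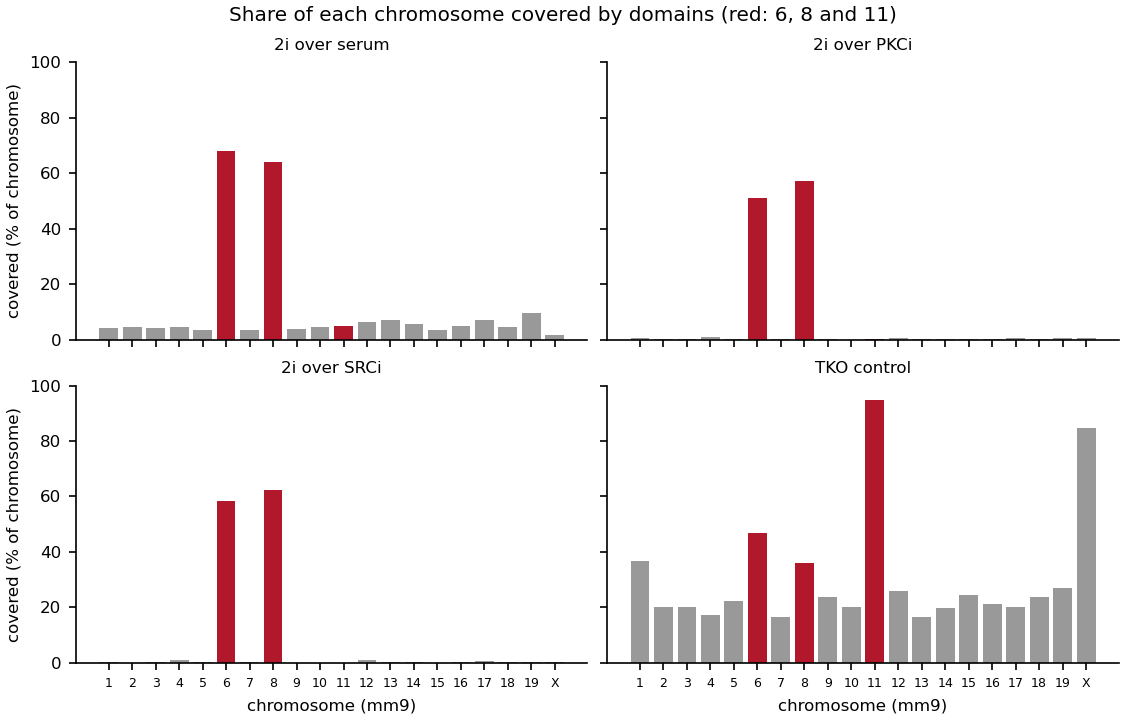
Percentage of each autosome and X (mm9) covered by domains of 4 sides, 1 bar per chromosome, with chromosomes 6, 8 and 11 in red. The 2i sides cover 51.0% to 68.0% of chromosomes 6 and 8, and the TKO control side covers 94.8% of chromosome 11.

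Knockdown of TDG, a DNA glycosylase that acts in removal of oxidised methylcytosine, gave 930 domains marked as higher than in its control, with a median of 483.5 kb and 896 Mb covered. Of these, 688 had scores above 0, toward the control (median 0.255, offset 0.286). The control side held 455 short domains with a median of 7 kb, covering 7.27 Mb. The longest knockdown domains lay on X and, as an empty block, on Y. They were led by X, 35168001 to 50829000, at 15.7 Mb, and the longest autosomal one was chromosome 4, 130120001 to 142028000, at 11.9 Mb. That X domain is not particular to the knockdown. The TKO control side held a domain with the same edges, and the longest DNMT1 control domain started at the same position. The longest TDG control domain was chromosome 4, 146776001 to 146994000, at 218 kb. The knockdown side covered 6.33% of its bases in the last 5 Mb of chromosomes, against 3.74% under shifts (adjusted p = 0.0240, permutation by circular shifts).

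In the TKO pair, 2071 domains were marked as higher in the control and 313 in TKO. Of the control domains, 1842 had scores below 0, toward TKO (median -0.57, offset -0.667). The control domains covered 850 Mb and the TKO domains 11.3 Mb. The control side covered 94.8% of chromosome 11, against 16.5% to 47.0% of the other autosomes and 84.5% of X. On chromosome 6, 10 windows of 5 Mb between 50 and 100 Mb, a segment picked after its values were seen, had a mean coverage of 84.3%, and the other 19 windows 29.5%. The longest TKO domains were chromosome 3, 8505001 to 9415000, at 910 kb, and chromosome 17, 24438001 to 24986000, at 548 kb.

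**Figure D2:**
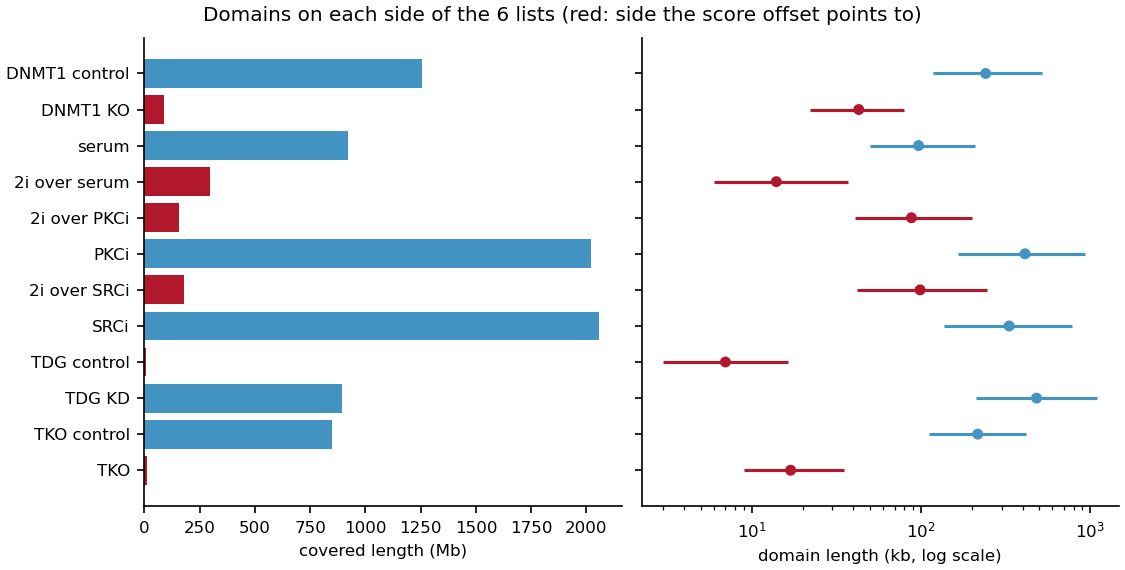
Covered length in Mb (bars) and domain length in kb on a log scale (points, median; lines, quartiles) for the 12 sides of the 6 lists, with the side the score offset points to in red. In every list the offset side covers less, from 7.27 Mb for TDG control to 294 Mb for 2i over serum.

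The question whether media and loss of DNMT1 or TDG place H2A.X at the same regions was addressed by overlap. Of the 1499 DNMT1 KO domains, 1054 met a domain higher in 2i than in serum, 3.20 times the 330 given by shifts, and shared bases were 4.48 times those of shifts. DNMT1 KO domains met serum domains less often, at 187 against 601 (ratio 0.311, and 0.112 at an overlap of 50% of the shorter domain). The adjusted p was 0.00250 for both counts, from the smallest p that the shifts can give. On the reduced autosomes the ratio of shared bases of DNMT1 KO with 2i was 8.89, and with the 50% of domains with the highest score it was 7.87. With directions pooled the ratio of counts was 1.12. Where domains of these lists overlapped, control went with serum and knockout with 2i, with a log2 odds ratio of 3.08 against -0.80 under shifts. Over all lists, shared bases passed the threshold above shifts where both sides were offset sides or both were not, and below shifts otherwise, in 56 of 60 pairings. Of the 48 pairings of lists that do not both name 2i, 44 did so. Pairings of the same pair of lists are linked, since the sides of a list exclude each other, so the 60 are not separate results. Serum with TKO control went against this (ratio 0.936), and 3 pairings did not pass the threshold.

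Of the DNMT1 KO domains, 192 met the TDG control side, against 19.2 under shifts (ratio 10.0), and 112 met TKO domains, against 17.2 (ratio 6.52). Whether these ratios differ from that with 2i was not tested. TDG control and TKO shared 79 of the 455 TDG control domains, where shifts gave 3.31 (ratio 23.9). Each of these had an adjusted p of 0.00250. With the 50% of domains with the highest score, the ratios were 24.6, 20.6 and 58.7 in turn, and with directions pooled TDG and TKO gave 0.966. TDG KD and DNMT1 KO overlapped less than under shifts, with a ratio of 0.869 by count (adjusted p = 0.0212, permutation by shifts) and 0.477 by shared bases (adjusted p = 0.00214). The count did not pass the threshold on autosomes (0.901), on the reduced autosomes (0.888), with the highest scores (0.941) or with uniform placement (1.03).

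The PKCi and SRCi sides had 1946 Mb in common, 91.4% of the bases covered by either. Each covers over 76.0% of the genome, and the shared bases were 1.12 times those of shifts and the count 1.03 times. Net coverage of the 2649 bins correlated at rho = 0.865, against 0.370 under shifts (adjusted p = 0.00214). Both lists use a 2i library, which may by itself give such likeness, and shifts do not give the value it would bring. The lists hold no read counts from which unchanged libraries could be simulated. Net coverage of the serum and 2i list ran opposite to that of the TDG list (rho = -0.581 against -0.104 under shifts, adjusted p = 0.00214, permutation by shifts). Serum and TDG KD domains shared 613 Mb, 1.65 times the value under shifts.

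The count of 2i domains over serum that met 2i domains over PKCi did not pass the threshold, at 882 against 920 (ratio 0.958, adjusted p = 0.229, permutation by shifts), while shared bases were 1.52 times those of shifts. On the reduced autosomes the count was 130 against 19.3, a ratio of 6.73, and shared bases were 18.6 times those of shifts. Both lists use a 2i library, whose noise may by itself give such overlap, so shifts do not give the value without a change in H2A.X.

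**Figure D3:**
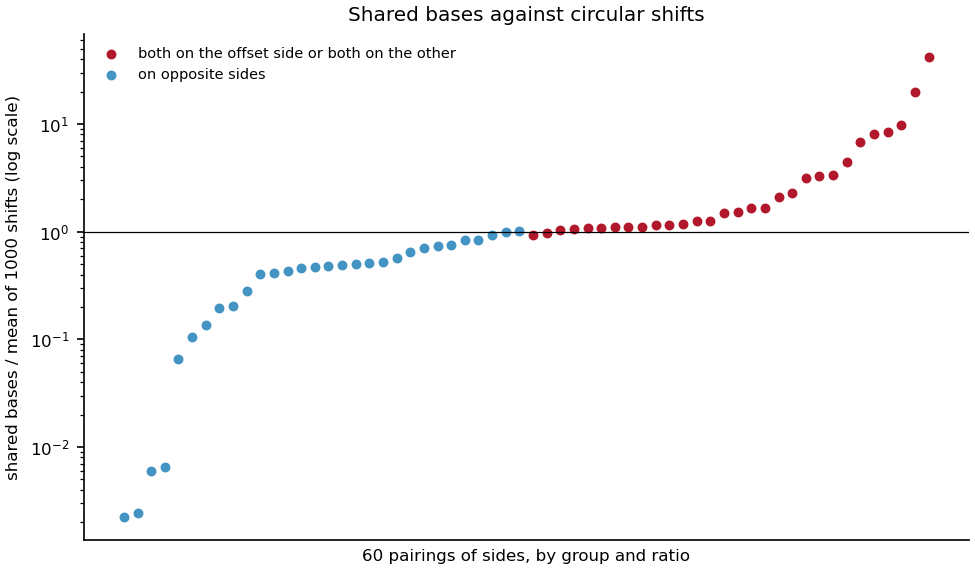
Shared bases divided by the mean of 1000 circular shifts (log scale) for the 60 pairings of sides, with 1 point per pairing, in red where both sides lie on the offset side or both on the other. Red points lie above 1 or blue points below 1 in 57 pairings, of which 56 passed the threshold and 1, at 0.998, did not.

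Some single places ranked among the highest scores in several lists. Chromosome 12, 68160001 to 68161000, scored -243 on the DNMT1 KO side and 165 on the 2i side over PKCi. Chromosome 11, 3000001 to 3100000, scored 94.8 on the 2i side over PKCi and 98.7 over SRCi. The place on chromosome 12 is only 1 kb long, and whether reads from repeats give such scores was not tested at single places. The longest region with domains of 3 or more lists on either side was X, 93604001 to 120158000, at 26554 kb. Such regions numbered 6805 and spanned 1864 of the 2655 Mb, so coinciding there is common. The longest among offset sides was chromosome 8, 50926001 to 53008000, at 2082 kb. It lies within 2i domains of the 3 lists that name 2i, which may share a library, so these are not separate results.

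By counts, 22 of the 60 pairings lay above shifts, 29 below and 9 on neither side of the threshold. The rule of offset sides held past the threshold in 45, and 6 went against it. These were TKO control with serum (0.858), PKCi (0.892), SRCi (0.934) and TDG KD (0.908), and TDG KD with SRCi (0.800) and 2i over SRCi (1.18). Of the domains on each side, 87.9% to 99.9% met some domain of another list. The PKCi and SRCi lists alone cover 82.0% and 84.1% of the genome, and these shares were not compared with chance. On the 2i side over serum 740 domains met no other list, and they had a median length of 17 kb, against 13 kb for the 2i domains that met another list (adjusted p = 4.8e-05 by label permutation). A longer domain meets another by 1 base more readily through its length alone, which the label permutation does not allow for. With this limit, the few unmatched domains of other sides were shorter where the test passed, at 33 kb against 414.5 kb for 9 PKCi domains, 53 kb against 344 kb for 57 SRCi domains, 31.5 kb against 218 kb for 8 TKO control domains and 13 kb against 97 kb for 3 serum domains.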

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

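The alternative chosen only after the results were seen is that of the reduced autosomes. All 45 direction odds and 41 of 45 alternative values of rho kept their direction and their side of the threshold, as did 55 of 60 ratios of shared bases. So did 68 of 78 overlap ratios, if turns with neither value past the threshold are let pass. These turns came at an overlap of 50% of the shorter domain. They were 2i over serum with 2i over PKCi, 0.958 to 1.04, and with 2i over SRCi, 0.981 to 1.05. Keeping the 50% of domains with the highest score lowered the counts by construction, to 1316 for DNMT1 control, 750 for DNMT1 KO, 2242 for serum, 3069 for 2i over serum, 347 for 2i over PKCi, 1264 for PKCi, 293 for 2i over SRCi, 1588 for SRCi, 228 for TDG control, 465 for TDG KD, 1036 for TKO control and 157 for TKO. In that setting pairings below chance went from 29 to 15 and those above from 22 to 26. On the reduced autosomes 2i domains fell to 130 over PKCi and 114 over SRCi. The overlap ratio of 2i over serum with 2i over PKCi, 0.958, turned to 2.54 with the highest scores, 1.22 with uniform placement and 6.73 on the reduced autosomes; with 2i over SRCi, 0.981 turned to 2.62, 1.29 and 6.29. TDG KD and TKO control, 0.908, gave 0.932 (adjusted p = 0.254, permutation by shifts) with the highest scores, and with uniform placement 1.02 by count. Its ratio of shared bases, 0.969 and not past the threshold, passed it at 0.891 with the highest scores, 0.862 on autosomes and 0.770 on the reduced autosomes, and turned to 1.24 with uniform placement. Serum and TKO control, 0.858 by count, gave 1.03 (adjusted p = 0.242, permutation) with uniform placement, and its ratio of shared bases, 0.936, turned to 1.20, which follows the offset sides. TDG control and TKO gave 0.966 with directions pooled, where the broad opposite sides enter. The share of 2i domains on chromosomes 6 and 8 went from 22.1% to 63.2% by covered bases and 16.9% with the highest scores against serum, from 77.3% to 95.6% and 68.9% against PKCi, and from 75.9% to 95.9% and 64.2% against SRCi. That of TKO control on chromosome 11 went from 4.20% to 13.6% and 7.92%. With the highest scores, rho changed sign, from 0.403 to -0.0381 for DNMT1 and TKO, from -0.123 to 0.0863 for PKCi and TKO and from -0.114 to 0.0836 for SRCi and TKO. The turned values did not pass the threshold (adjusted p = 0.723, 0.195 and 0.184 in turn, permutation by shifts), with shift means of -0.0312, 0.0647 and 0.0607. For TDG and TKO rho went from -0.0975 to 0.118 on the reduced autosomes, both above their shift means of -0.129 and 0.0144. The ratio of serum bases in the last 5 Mb passed the threshold at 1.48 within 10 Mb and at 1.74 with the highest scores, and that of DNMT1 control passed it at 1.29 within 10 Mb. Except where stated the cause was not tested. The planned tests of genes at domains were not run, since mm9 annotation was not used here. No paired analysis was possible because each condition has 1 library. Depth is unknown and its limits could not be measured.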

Other observations

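Tests chosen only after the result was seen were those on chromosomes 6 and 8, on X, and on DNMT1 KO with TDG control; the bounds for the count of pairings and for the correlation of scores were set before those values were computed, but after the score offsets, the regions and their median scores had been seen.

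The offset sides of all 6 lists coincided in 35 regions spanning 0.969 Mb on 14 chromosomes. The longest were chromosome 4, 146776001 to 146900000, at 124 kb, chromosome 18, 3000001 to 3106000, at 106 kb, and chromosome 11, 3000001 to 3100000, at 100 kb. Mitochondrial DNA lay on the offset side in 5 lists, and on the TDG KD side, with a score of -169, in the TDG list.

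The 2i side covered chromosomes 6 and 8 far more than other autosomes in each of the 3 lists that name 2i. A difference not scaled for depth would raise all autosomes alike, and the lower of chromosomes 6 and 8 was covered at least 6.67 times as much as the highest other autosome. Extra copies of chromosomes 6 and 8 in the cells of the 2i library stay open. The 2i side led in at least 96% of their 5 Mb windows in each list, but the chromosomes were picked for that coverage. Their lowest windows, at 8.52% against serum, 2.40% against PKCi and 4.04% against SRCi, lay below the highest windows elsewhere. Extra copies need not lift every window above all others, so these low windows do not decide. An effect of 2i medium was not tested apart from extra copies, since no other library analysed here was grown in 2i. The TKO control side's 94.8% of chromosome 11 is given as a value.

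Shared bases lay above the shift mean when both sides lay on the offset side, or both on the other, and below it otherwise, in 57 of 60 pairings, 1 of which lay at chance (2i over PKCi with TKO control, 0.998), and counts did so in 49. Pairings of the same pair of lists are linked, so these are not 60 separate results. A difference not scaled for depth may give this pattern, as the deeper library would lead at places with more reads and the shallower where there are few. The side opposite the offset covered X more than every autosome in 5 of 6 lists, chromosome 11 being the exception in the TKO list. This leaves a difference not scaled for depth open in X, which would hold fewer reads in male cells: Y, 2779001 to 2797000, was scored in all 6 lists, but repeat reads could give that, and the labels give no sex. H2A.X at the same places after loss of DNA methylation would also give the overlap of DNMT1 KO with 2i, but DNMT1 KO shared bases with TDG control at 19.9 times chance and with 2i at 4.48, sides of unequal size, so the overlaps in the report cannot be told apart from unequal depth for DNMT1 KO and 2i.

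Regions on the offset side in all 6 lists may hold reads from repeat copies that the genome build holds fewer times. Score size across the 35 regions should then rank alike in lists that name no condition in common. The median Spearman's rho over 12 such pairs of lists was 0.453, between the bounds of 0.5 and 0.3, so the test leaves the explanation open. Each region took the score of the whole domain that holds it. Some neighbouring regions lie in the same domain, so the 35 values of a list are not all separate. Some control libraries enter only through the lists, so whether such pairs share a library is not known. No biological explanation was tested for these regions.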
